A study of Mus musculus with 7 samples.

How the data were processed

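Total RNA was measured by paired-end sequencing in 7 tumour samples, 3 with STAT6 WT and 4 with STAT6 D419N. The deposited table holds raw read counts per Ensembl gene, as whole numbers and with no normalization by the authors. The submitters' processing notes name Trimmomatic 0.32, FastQC 0.11.2, STAR 2.3.0e, featureCounts 1.4.4 and the mm10 build. The library preparation (poly-A selection or ribosomal RNA depletion), the gene annotation, the strand setting of the counting and the rule that chose the table's rows are not given in the sources used here. The table has 20178 genes, 366 of them at 0 in every sample. Gene symbols, biotypes and coordinates came from GENCODE mouse release M21 on the same build by Ensembl identifier, which matched 20077 genes and left 101 without a match. Transcript length and GC content were taken from 1 transcript per gene, by APPRIS principal rank, then support level, then the shortest of the principal ones. This can miss the expressed transcript: Rps20 is entered at 3706 bases and Vegfa at 654. Library totals ran from 22894403 to 38199980 counts, so 1 CPM stands for about 22.9 to 38.2 counts and genes near that level carry large counting error.

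Counts were tested in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM factors and the quasi-likelihood F test, genotype as the only term, and Benjamini-Hochberg adjustment over 12140 genes at a two-sided threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F, which is approximate. CPM values are counts for each 1e6 counts of the TMM-scaled library size. The labels give each sample its own mouse as batch, so batch could not be a term. Replicate numbers occur in both groups without a stated pairing, and deviations from the group mean of same-numbered samples correlated across genes at -0.01, 0.01 and -0.07, so the replicate block was run as an alternative only.

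The 40 gene lists, the test, the rule for named genes and all settings not named below as added were set before the data were examined. Some genes belong to several lists, so list results are not independent of each other. The rule named Stat6, Myc, Il4ra, Ccl17 and Fcer2a always. It added the 12 largest rises and the 12 largest falls among genes with an adjusted p below 0.05, non-overlapping groups and a mean of at least 50 counts, leaving out predicted genes and immunoglobulin or T cell receptor segments. It also named up to 4 members of each list with the smallest p, of which the text gives examples. Hspa1a, Malat1, Gm42418, Gm26917, mt-Rnr1, mt-Rnr2 and the immunoglobulin segments lie outside the rule and were chosen after their values were seen. A gene "rose" or "fell" where its adjusted p over all genes was below 0.05. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 (preset correlation of 0.01 between genes) on log2 CPM with a prior count of 2. The alternatives were an estimated correlation per list and fry.

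The settings tried for the counts of genes were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a filter of at least 50 counts in 3 samples, DESeq2 1.42.0, limma-voom, the robust quasi-likelihood fit, the replicate block, a test against a fold of 1.5, removal of immunoglobulin and T cell receptor segments, and leaving out each library. After a trend with transcript length was seen, a per-library offset was added from natural splines with 5 degrees of freedom for log2 length and for GC content, fitted to genes with a mean log2 CPM above 1. Runs without WT replicates 1 and 2, without ribosomal RNA repeat and structural RNA genes, and with the offset and the replicate block together were also added. Where WT replicate 3 was the only WT library, it was assumed to vary like the D419N group. The WT libraries varied more: pairs of them had a Pearson correlation of log2 CPM of 0.9776 to 0.9859. Pairs of D419N libraries had 0.9863 to 0.9943. Calls and adjusted p from that run may therefore be too favourable and do not measure robustness.

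Library measures were compared by a two-sided exact permutation test on the difference of means over all 35 splits, with Benjamini-Hochberg adjustment over 10 measures. Shares in single libraries carry 95% Wilson intervals. The test was tested on simulated data. Counts drawn with no trend at the dispersions estimated per gene gave 5 false calls in a fit of 12140 genes. They recovered 53.7%, 62.7% and 89.4% of genes changed by 1.5-, 2- and 4-fold. Genes were drawn independently, with the same dispersion in both groups. These rates therefore do not cover shifts shared by many genes of a library, or a wider spread among the WT libraries. With a simulated length trend, 1005 unchanged genes were called without the offset and 9 with it. That trend was built from the same transcript lengths that the offset uses. It therefore cannot show how the offset fares where an entered length is wrong.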

Results

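RNA was sequenced from 7 samples of mouse Eµ-Myc lymphoma, a B cell lymphoma driven by a Myc transgene under the immunoglobulin heavy chain enhancer. The cells carried either wild-type STAT6 (WT, n = 3) or STAT6 with the D419N substitution (n = 4), a change in the DNA-binding domain that recurs in human germinal centre lymphomas. STAT6 is the transcription factor that the interleukin 4 receptor activates. Each sample came from a different C57BL6 mouse, in which cells injected by the tail vein had grown for 11 days into lymph node tumours before selection for the B cell surface protein CD19. The WT replicates held 35035869, 25163828 and 27333873 counts over 20178 genes, and D419N replicates 1 to 4 held 24683178, 28680956, 22894403 and 38199980. The comparison of D419N with WT asks which transcripts differ with the STAT6 genotype.

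Of 30 measured immediate early genes, 10 rose and 1 fell in tumour cells with STAT6 D419N, with Cd83, Egr3, Nr4a1 and Dusp5 among the rises, and the WT libraries differed widely on this list (mean log2 CPM of 5.22, 3.27 and 6.58). The transcription factor genes Myc, Rel, Irf4 and Bcl6 rose, as did 6 of 18 mature follicular B cell genes, including Fcer2a, Ccr7 and S1pr1, although the follicular list did not pass as a whole (camera adjusted p = 0.208). All 38 ribosomal protein genes and 28 of 30 oxidative phosphorylation genes fell, with median log2 fold changes of -0.52 and -0.32, and with an offset for transcript length and GC content 32 and 5 fell (medians -0.26 and -0.12). Of 19 chromatin regulator genes, 15 rose, Setd2 and Tet2 among them, and 9 rose with the offset. None of these lists passed with an estimated correlation between genes (adjusted p = 0.198 for chromatin regulators and 0.959 for each of the others).

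In the edgeR test, 4077 of 12140 genes changed at an adjusted p below 0.05, with 2027 higher and 2050 lower in D419N, and 5393 passed at an unadjusted p below 0.05. This balance depended on the scaling, with 1713 higher and 2577 lower under upper-quartile factors and 2114 and 1869 under RLE factors. The shares of all tested genes that rose and fell are the background for the list counts below. A list count near them is no sign of a change in that list. Of the changed genes, 1065 differed by more than 1.5-fold, and those beyond 2-fold comprised 295 higher and 101 lower genes. The groups did not overlap for 5103 genes (42.0%), where chance gives 5.71%. Transcript length moved with genotype: across 9284 protein-coding genes, the log2 fold change had a Spearman correlation of 0.60 with transcript length and of -0.24 with GC content (genes are not independent replicates). Over 10 length bins, the shortest had a median log2 fold change of -0.34 and the longest 0.42. With a per-library length and GC offset, an alternative added after the trend was seen, 2139 genes changed (969 higher, 1170 lower), of which 1602 kept the call and the direction of the uncorrected test. Without WT replicates 1 and 2, which stood farthest from the other libraries, 2234 genes changed (1411 higher, 823 lower). With the replicate number as a blocking term, 2682 genes changed, a test against a fold of 1.5 gave 113, and leaving out D419N replicate 2 reduced the lower genes to 1351. Every D419N library name carried a prefix that no WT library had, so any effect of that prefix and the genotype cannot be told apart. Among WT libraries, replicate 3 carried another prefix than replicates 1 and 2.

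**Figure D1:**
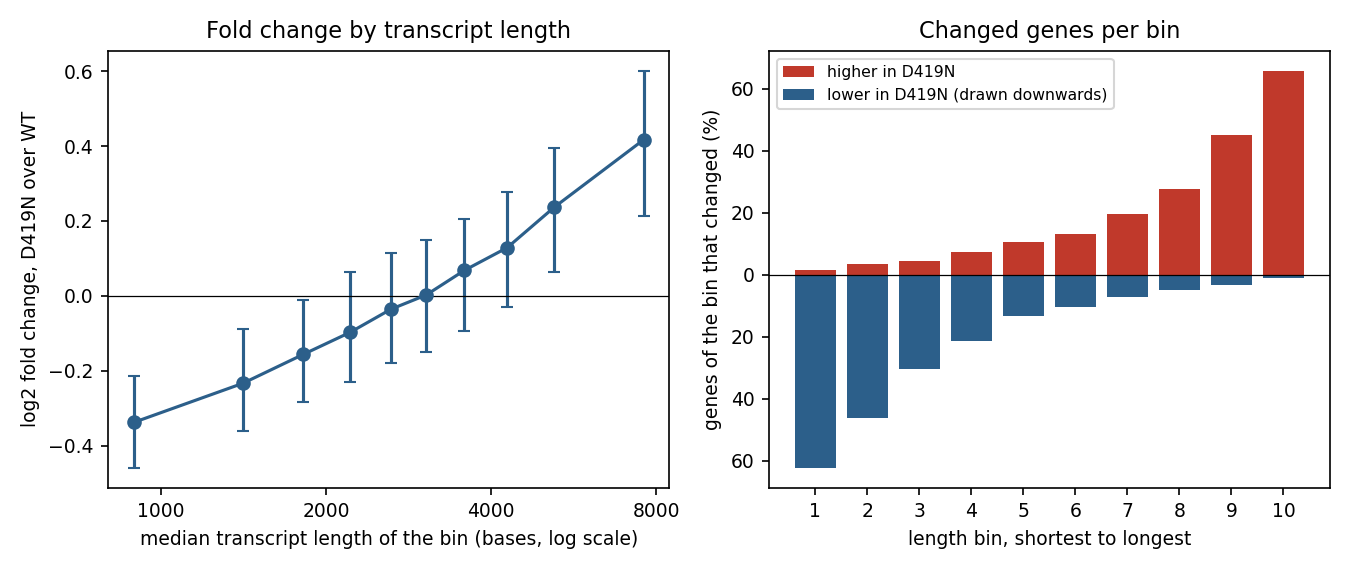
Left: median log2 fold change (D419N over WT) of protein-coding genes in 10 bins of transcript length, with bars from the lower to the upper quartile of genes; the x axis is on a log scale. Right: percent of the genes in each bin that were higher or lower in D419N; medians run from -0.34 in the shortest bin to 0.42 in the longest.

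Stat6 itself (ENSMUSG00000002147, mm10 chromosome 10, 127642986 to 127660957, plus strand) measured 224 ± 11.1 CPM in WT (SD, n = 3) and 294 ± 10.8 CPM in D419N (SD, n = 4), a log2 fold change of 0.39 ± 0.06 (SE; adjusted p = 0.00155). All 4 D419N values lay above the 3 WT values, and gene totals cannot separate the WT from the D419N allele or an introduced copy from the host gene. Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474, plus strand), the interleukin 4 receptor chain upstream of STAT6, measured 58.2 ± 9.23 CPM in WT (SD, n = 3) and 60.5 ± 7.57 CPM in D419N (SD, n = 4) and did not pass (log2 fold change 0.06 ± 0.13, adjusted p = 0.763). Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175, minus strand), which encodes the low-affinity IgE receptor CD23 and is a classic interleukin 4 target in B cells, rose (8.85 ± 3.57 against 21.6 ± 5.41 CPM, WT against D419N, SD, n = 3 and 4; log2 fold change 1.28 ± 0.29, adjusted p = 0.0105). Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374, plus strand), whose count sums the transgene and the host gene, measured 677 ± 225 CPM in WT (SD, n = 3) and 1520.0 ± 174 CPM in D419N (SD, n = 4) (log2 fold change 1.17 ± 0.20, adjusted p = 0.00322). Ccl17, another interleukin 4 target, has no row in the count table and was not analysed.

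**Figure D2:**
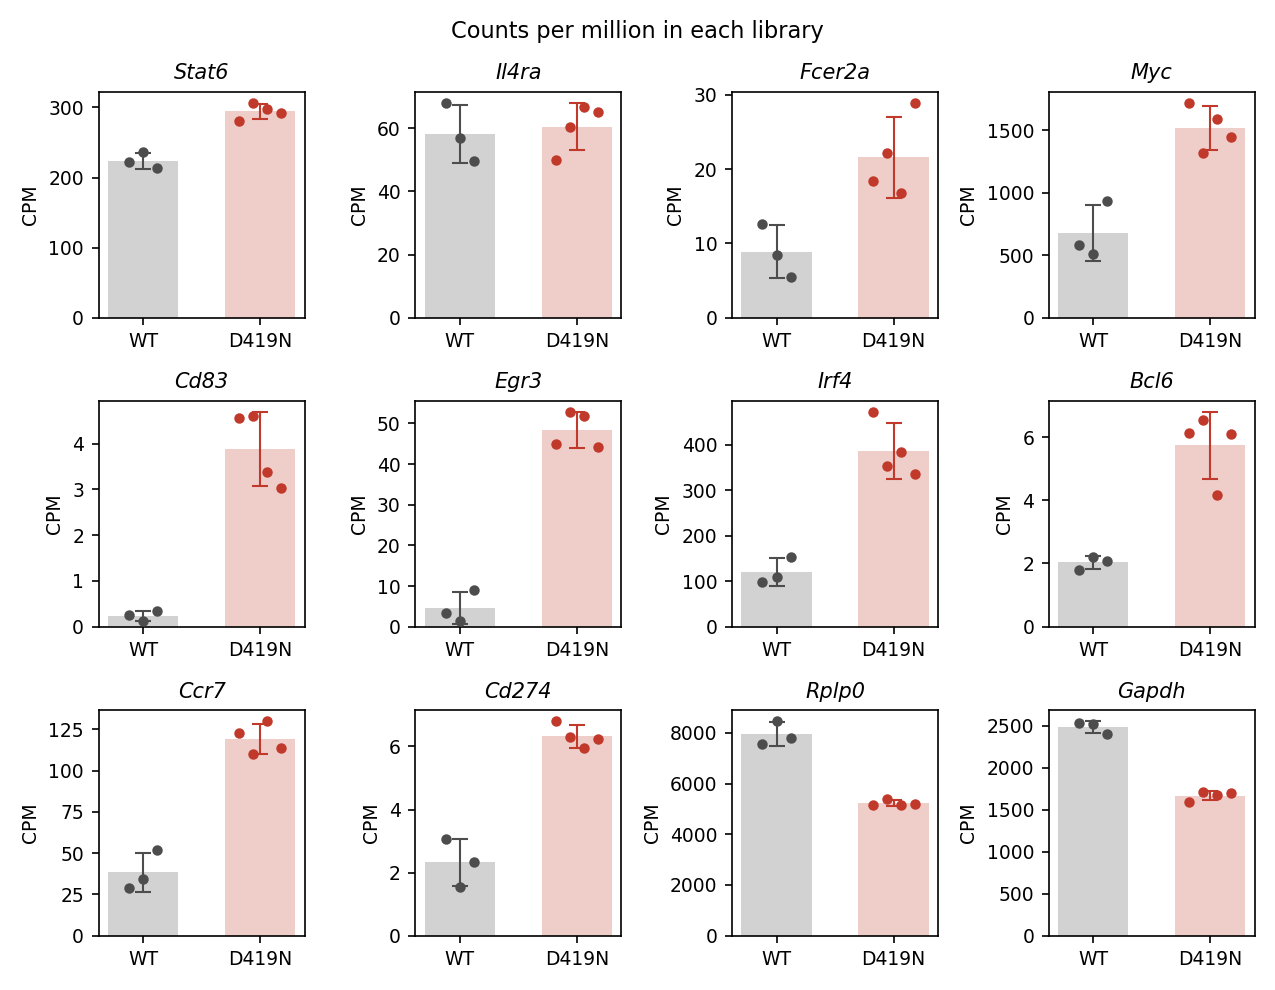
Library-scaled expression (CPM, counts for each 1e6 scaled library counts) of 12 genes in each library, with bars at the group mean and whiskers of 1 SD (WT n = 3, D419N n = 4). Stat6, Fcer2a, Myc, Cd83, Egr3, Irf4, Bcl6, Ccr7 and Cd274 were higher in every D419N library than in any WT library, Rplp0 and Gapdh were lower in every one, and Il4ra overlapped (58.2 ± 9.23 against 60.5 ± 7.57 CPM).

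The 12 largest rises by the fixed rule were Cd83 (3.96 ± 0.35), Irs2 (3.86 ± 0.38), Egr3 (3.38 ± 0.46), Tent5c (3.28 ± 0.83), Zbtb10 (2.95 ± 0.46), Gpr183 (2.84 ± 0.46), Fosl2 (2.84 ± 0.56), Trib1 (2.78 ± 0.68), Dusp10 (2.78 ± 0.32), Sik1 (2.75 ± 0.60), Nr4a2 (2.70 ± 0.58) and Bhlhe40 (2.65 ± 0.66), as log2 fold change ± SE. Cd83 encodes an activation marker of B cells and dendritic cells, and had 21 counts in all WT libraries together and 445 in D419N. Irs2, an adaptor of insulin and interleukin 4 receptors, measured 3.14 ± 0.848 CPM in WT (SD, n = 3) and 45.0 ± 17.1 CPM in D419N (SD, n = 4). Egr3, Fosl2, Nr4a2 and Bhlhe40 encode transcription factors that respond to stimulation. All 12 also passed with the length and GC offset, with adjusted p from 0.00100 for Cd83 to 0.0422 for Tent5c. Tent5c and Bhlhe40 did not pass with the replicate block (adjusted p = 0.0628 and 0.0553) or against WT replicate 3 alone. The other 10 kept their calls with the replicate block. WT replicate 3 set the size of some rises: without it Tent5c was at 5.32 and Trib1 at 4.24, so the order of the rises rests in part on that library.

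The 12 largest falls held many non-coding RNAs. Rmrp (log2 fold change -4.87 ± 0.65), Rn7sk (-4.38 ± 0.37) and Rpph1 (-2.64 ± 0.45), the RNAs of the ribonuclease MRP, 7SK and ribonuclease P particles, fell most, although Rmrp rested on 17 counts in all D419N libraries together against 344 in WT. Kcnq1ot1 (-1.83 ± 0.43), Mir6236 (-1.64 ± 0.46) and Snord104 (-1.52 ± 0.15) also fell. The genes annotated as coding were Cox6a2 (-1.83 ± 0.41), Lars2 (-1.75 ± 0.39), Ccdc40 (-1.68 ± 0.35), Slc6a19 (-1.66 ± 0.51), Ltb (-1.61 ± 0.41) and Pllp (-1.35 ± 0.21). The counts over a ribosomal RNA repeat on chromosome 17 moved with these: Gm42418 (39846958 to 39848788) and Gm26917 (39843013 to 39846341) together took 0.764 ± 0.531% of WT counts (SD, n = 3) and 0.126 ± 0.0164% of D419N counts (SD, n = 4; exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.0408 over 10 library measures). WT replicate 2 alone reached 1.37%, against 0.506% and 0.412% in WT replicates 1 and 3. Lars2 followed the repeat over WT replicates 1 to 3, at 1008.0, 2752.9 and 928.6 CPM against 3550.8, 10357.5 and 3263.3 CPM for Gm42418. Lars2 was removed with the repeat in the run without ribosomal RNA repeat and structural RNA genes. Its fall may therefore not be that of a coding transcript, which was not tested. The falls of Kcnq1ot1 and Lars2 were -0.94 and -1.05 without WT replicate 2, and that of Ltb was -0.74 without WT replicate 1. Without WT replicate 2, Mir6236 had a log2 fold change of -0.82 and did not pass (adjusted p = 0.0778). It also lost its call without D419N replicate 1, 2 or 3 (adjusted p from 0.0530 to 0.0607). Slc6a19 lost its call without WT replicate 1 (-1.13, adjusted p = 0.122) or 3, or without D419N replicate 2, 3 or 4 (adjusted p from 0.0517 to 0.0912). Cox6a2, Lars2 and Ccdc40 did not pass against WT replicate 3 alone (adjusted p = 0.0724, 0.0602 and 0.115), and Kcnq1ot1 did not with the replicate block (adjusted p = 0.0561). With the length and GC offset, Ltb did not pass (log2 fold change -1.31, adjusted p = 0.0727).

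Of 13 measured interleukin 4 and STAT6 target genes, 4 rose and none fell, over all genes and also when adjusted over the list alone. These were Fcer2a, Nfil3 (log2 fold change 2.25 ± 0.27), Egr2 (2.34 ± 0.77) and Il4i1 (0.30 ± 0.08). Nfil3 encodes an interleukin-responsive transcription factor and Il4i1 an amino acid oxidase induced by interleukin 4. The list as a whole did not pass camera (adjusted p = 0.464), and fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.0308; camera gave 0.959 with an estimated correlation. Egr2 lost its call without WT replicate 1 (adjusted p = 0.104) or without any single D419N library (adjusted p from 0.0733 to 0.0941), and was at 3.57 without WT replicate 3. Il4i1 lost it without WT replicate 2 (adjusted p = 0.0525) or D419N replicate 2 (adjusted p = 0.0504). Of 24 JAK-STAT pathway genes, 4 rose and none fell, and 1 rose when adjusted over the list alone. Over all tested genes 2027 of 12140 rose, a like share, so this count of rises is no more than the background. Jak2 rose by 0.59 ± 0.13 on the log2 scale, and the feedback inhibitor gene Socs3 (1.72 ± 0.53) and the kinase gene Pim1 (1.56 ± 0.49) depended on single libraries. Without any 1 of the D419N libraries neither passed, with adjusted p from 0.0613 to 0.0931 for Socs3 and from 0.0659 to 0.0831 for Pim1, nor did Socs3 without WT replicate 3 (adjusted p = 0.0651) or Pim1 without WT replicate 1 (adjusted p = 0.0859). JAK-STAT rises numbered 1 without D419N replicate 1, 2 or 3 and 2 without WT replicate 3 or D419N replicate 4 and 7 without WT replicate 1. JAK-STAT falls numbered 1 without WT replicate 2. Interleukin 4 target rises numbered 2 without D419N replicate 2. Interleukin 4 target falls numbered 1 without WT replicate 2 or 3. With the offset, 3 rose and 0 fell among the interleukin 4 targets and 2 rose and 0 fell in the JAK-STAT list, where Jak2 did not pass (0.32, adjusted p = 0.127). Egr2 and Pim1 also lost their calls with it at little change in fold (2.34 and 1.60, adjusted p = 0.0676 and 0.0519).

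In the germinal centre list, 5 of 15 measured genes rose and none fell (5 when adjusted over the list alone), with a median log2 fold change of 0.61. They included Bcl6 (1.5 ± 0.20), the repressor that defines germinal centre B cells, Bach2 (0.89 ± 0.08), the migration regulator Gna13 (0.89 ± 0.08) and Gpr183, a receptor that draws B cells away from germinal centres. The list passed camera (adjusted p = 0.00629) but not with an estimated correlation (adjusted p = 0.277 with an estimated correlation), and with the length and GC offset 5 genes still rose. In the mature follicular list, 6 of 18 genes rose and none fell (6 when adjusted over the list alone). Ccr7 (1.64 ± 0.18) and S1pr1 (1.64 ± 0.19), receptors that guide lymphocytes into and out of lymph nodes, rose from 38.3 to 119 CPM and from 21.5 to 67.1 CPM; the list did not pass camera (adjusted p = 0.208) or fry (adjusted p = 0.0526), and passed camera with the offset (adjusted p = 0.0376) but not, without the offset, with an estimated correlation (adjusted p = 0.959). With the offset, 5 of these genes rose, and Zfp318 did not (0.55 before, 0.05 after, adjusted p = 0.718). Follicular falls numbered 1 without WT replicate 2 or D419N replicate 4.

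Plasma cell genes went both ways, with 3 of 11 rising and 3 falling (also when adjusted over the list alone). Irf4 (1.69 ± 0.18), which directs plasma cell and activated B cell fates, rose from 120 ± 30.2 to 387 ± 60.9 CPM (SD, n = 3 and 4), while Mzb1 (-0.76 ± 0.13) and Sec61b (-0.49 ± 0.05), both short transcripts of the secretory pathway, fell; neither fall passed with the length and GC offset (adjusted p = 0.0727 and 0.122). Among 18 B cell identity genes, 2 rose and 4 fell (also when adjusted over the list alone). Pax5 (0.45 ± 0.08) was higher, and the receptor chain genes Cd79a (-0.47 ± 0.10) and Cd79b (-0.46 ± 0.07) were lower. With the offset, 1 gene of this list rose and none fell, and Pax5 measured 0.07. Of 14 precursor B cell genes, 2 rose and 1 fell (also over the list alone): Akap12 (0.83 ± 0.12) and Cd24a (0.49 ± 0.10) were higher and Vpreb3 (-0.45 ± 0.07) was lower. Among 24 B cell receptor signalling genes, 1 rose, Malt1 (0.40 ± 0.09), and 1 fell, Blnk (-0.26 ± 0.07); over the list alone, 1 rose and none fell. Blnk lost its call without WT replicate 1 (log2 fold change -0.18, adjusted p = 0.0812) and without each of D419N replicates 1 to 3. With the offset, 2 rose and 0 fell in the plasma cell list, 2 rose and 0 fell in the precursor list and 2 rose and 0 fell in the receptor signalling list, without Malt1 (0.10, adjusted p = 0.450). Precursor rises numbered 5 without D419N replicate 4. Receptor signalling rises numbered 3 without D419N replicate 4 and 7 without WT replicate 1. Receptor signalling falls numbered 0 without WT replicate 1 or D419N replicate 1 or 2.

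Immediate early genes had the highest median among the lists with at least 5 measured genes other than the cell markers. Of 30 measured genes, 10 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 1.49. Nr4a1 (1.76 ± 0.27) and Dusp5 (2.35 ± 0.42), which respond to antigen receptor and MAP kinase signals, rose with Cd83 and Egr3. Hspa1a, a heat shock gene on the same list, fell (-1.97 ± 0.52), and lost its call without WT replicate 3, D419N replicate 1 or D419N replicate 3 (adjusted p from 0.0531 to 0.0708). The list passed camera (adjusted p = 1.99e-05), not with an estimated correlation (adjusted p = 0.959 with an estimated correlation) and not fry (adjusted p = 0.115). WT libraries differed widely: mean log2 CPM over the list was 5.22, 3.27 and 6.58 in WT replicates 1 to 3 and between 7.04 and 7.25 in D419N. WT replicate 3, the highest of the WT libraries, also differed from the other WT libraries in its name prefix. Against WT replicate 3 alone, the list median was 0.57. Without WT replicate 1, 7 genes rose and 1 fell. The list median was 2.33 without WT replicate 3. Immediate early rises numbered 22 without WT replicate 3. Immediate early falls numbered 0 without WT replicate 3 or D419N replicate 1 or 3 and 3 without WT replicate 2. With the length and GC offset, 9 rose and 1 fell.

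Among 23 NF-kB target genes, 5 rose and 2 fell (also when adjusted over the list alone), among them Rel (2.03 ± 0.19), a subunit of NF-kB itself, and Nfkbiz (1.56 ± 0.35). Map3k14 fell (-0.41 ± 0.12), a call that ended when any 1 of the 7 libraries but WT replicate 3 was left out (adjusted p from 0.0556 to 0.126). Of 10 measured cytokine and chemokine genes, 3 rose and 4 fell (3 and 5 over the list alone). Vegfa (0.86 ± 0.17) was higher, and the lymphotoxin genes Lta (-1.10 ± 0.27) and Ltb (-1.61 ± 0.41) and Il16 (-0.54 ± 0.12) were lower. WT replicate 1 set much of the lymphotoxin values: without it Lta was at -0.64 and Ltb at -0.74, and both still passed (adjusted p = 0.0206 and 0.00191). Of 10 checkpoint genes, 2 rose and 1 fell (2 and 2 over the list alone), and Cd274, which encodes PD-L1, rose (1.44 ± 0.22) from 2.32 to 6.33 CPM. In adhesion and migration, 7 of 23 genes rose and 3 fell (also over the list alone), including the integrin gene Itga6 (0.52 ± 0.07). Ccr7, S1pr1 and Gpr183 are on this list and on the follicular list, and Gpr183 is also on the germinal centre list. The rises of these lists are therefore in part the same genes. None of the 30 interferon response genes rose and 1 fell, Bst2 (-0.56 ± 0.16; none over the list alone), and Bst2 lost its call without WT replicate 1 (-0.34, adjusted p = 0.0760) and without each of D419N replicates 1 to 3. With the offset, 4 rose and 1 fell among NF-kB targets, 2 rose and 1 fell among cytokines, 2 rose and 0 fell among checkpoint genes, 5 rose and 1 fell in adhesion and 0 rose and 0 fell in the interferon list, and Lta did not pass (-0.91, adjusted p = 0.0596). NF-kB rises numbered 2 without D419N replicate 1, 2 or 3. NF-kB falls numbered 0 without WT replicate 1 or D419N replicate 1, 2 or 4 and 1 without WT replicate 2 or 3. Cytokine rises numbered 1 without WT replicate 2 or 3 or D419N replicate 1 or 3. Checkpoint rises numbered 1 without WT replicate 1 or 3 or D419N replicate 1 or 2. Checkpoint falls numbered 0 without WT replicate 1 or 2 or D419N replicate 1, 2 or 3. Interferon rises numbered 1 without WT replicate 1 or 3. Interferon falls numbered 0 without WT replicate 1 or D419N replicate 1, 2 or 3.

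All 38 ribosomal protein genes fell (38 over the list alone). Rplp0 (-0.60 ± 0.05), Rpl18 (-0.61 ± 0.05) and Rps6 (-0.50 ± 0.04) are examples, and ribosomal protein genes took 16.4 ± 1.14% of counts in WT (SD, n = 3) and 11.98 ± 0.274% in D419N (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0408). Most of these transcripts are short, and with the length and GC offset 32 fell, with a median of -0.26. Of 30 oxidative phosphorylation genes, 28 fell (28 over the list alone), among them Ndufb5 (-0.49 ± 0.05) and Cox4i1 (-0.49 ± 0.06); with the offset 5 fell, without Cox4i1 (-0.17, adjusted p = 0.0596), with a median of -0.12. Of 19 glycolysis genes, 3 rose and 8 fell (3 and 9 over the list alone): Gapdh (-0.58 ± 0.05), Pgk1 (-0.36 ± 0.05) and Gpi1 (-0.31 ± 0.05) fell and the hexokinase gene Hk2 rose (0.62 ± 0.07). With the offset, 1 rose and 5 fell in the glycolysis list, and all 4 of these examples kept their calls (adjusted p from 0.00719 to 0.0160). Of 19 chromatin regulators mutated in lymphoma, 15 rose and none fell (15 and 1 over the list alone), including Setd2 (0.77 ± 0.05), Tet2 (0.99 ± 0.08), Crebbp (0.86 ± 0.07) and Arid1a (0.74 ± 0.07). These transcripts are long, and with the offset 9 rose, with the median moving from 0.65 to 0.32. Glycolysis rises numbered 1 without WT replicate 2. Glycolysis falls numbered 5 without WT replicate 2 or 3 or D419N replicate 1, 2 or 3. Chromatin regulator falls numbered 1 without WT replicate 1. The ribosomal protein, oxidative phosphorylation and chromatin lists passed camera (adjusted p = 2.61e-18, 6.60e-09 and 9.91e-07), and none of them passed with an estimated correlation (adjusted p = 0.959, 0.959 and 0.198 with an estimated correlation).

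**Figure D3:**
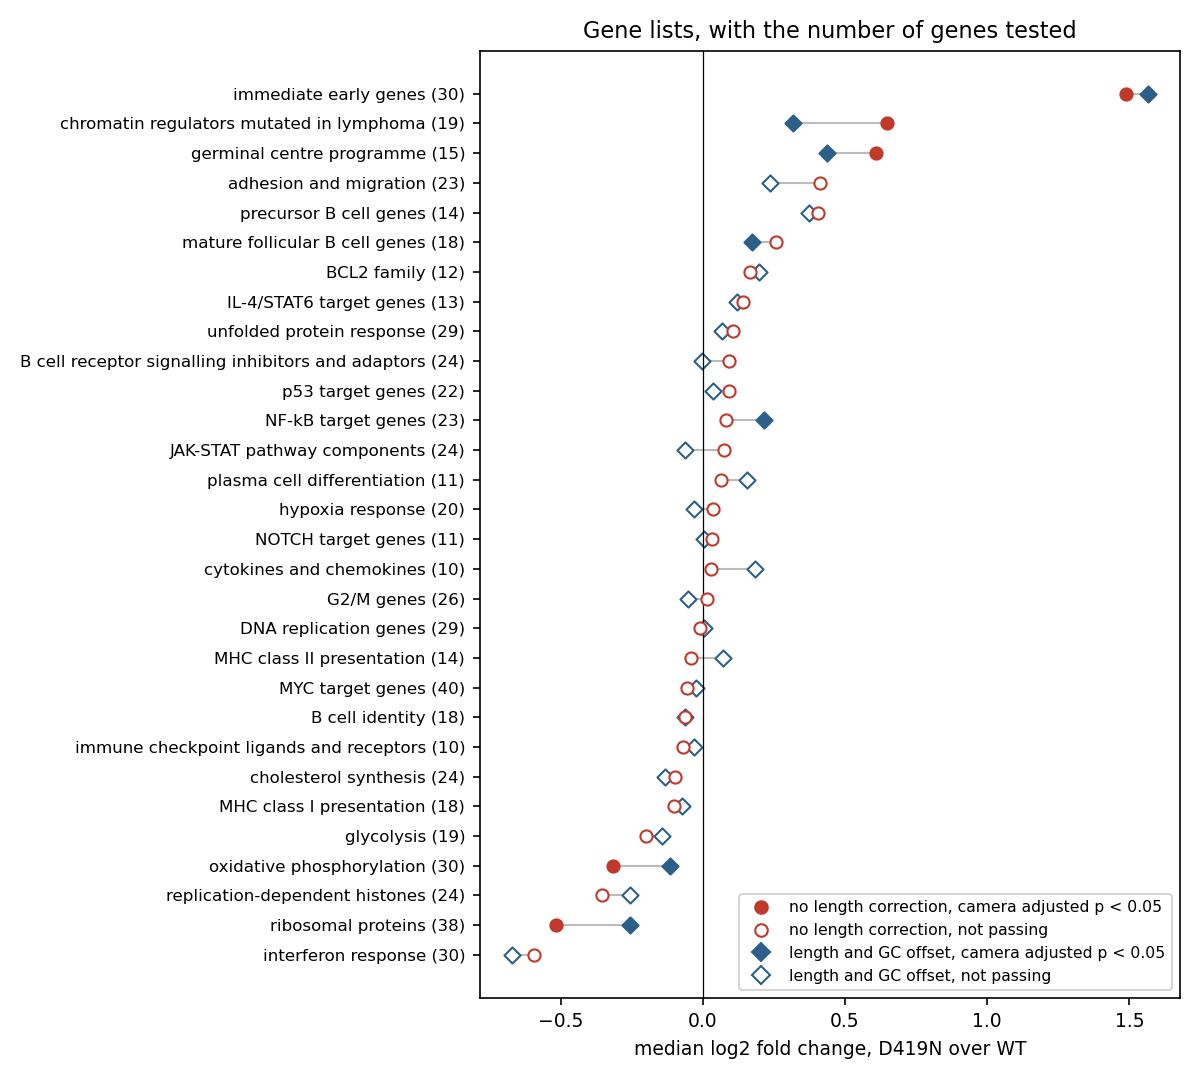
Median log2 fold change (D419N over WT) of each fixed gene list, with the number of genes tested in brackets. Circles are medians of the uncorrected test and diamonds those with the length and GC offset, and filled symbols passed camera at an adjusted p below 0.05; the ribosomal protein median moves from -0.52 to -0.26 while the immediate early median stays at 1.49 and 1.57.

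Of 40 MYC target genes, 5 rose and 8 fell (also over the list alone): Odc1 (0.37 ± 0.08) rose, and Ran (-0.51 ± 0.06) and Prdx4 (-0.51 ± 0.04) fell. Of 26 G2/M genes, 5 rose and 4 fell (6 and 4 over the list alone), and the long transcripts Mki67 (0.53 ± 0.06), Cenpf (0.76 ± 0.09) and Cenpe (0.59 ± 0.11) were higher, whereas with the offset none of the list rose and 1 fell. Of 29 DNA replication genes, 5 rose and 4 fell (5 and 5 over the list alone), including Dtl (0.49 ± 0.06) and Gins2 (-0.36 ± 0.06). Of 24 replication-dependent histone genes, 2 rose and 1 fell (none over the list alone). Of 22 p53 target genes, 5 rose and 1 fell (also over the list alone), and the growth arrest gene Sesn1 was higher (0.53 ± 0.14). Of 12 BCL2 family genes, 3 rose and 3 fell (4 and 4 over the list alone). The survival gene Mcl1 rose (0.86 ± 0.19) and the death effector gene Bax fell (-0.32 ± 0.06), the latter at a log2 fold change of 4.96e-05 with the offset. After the offset, 3 rose and 4 fell among MYC targets, 2 rose and 4 fell in replication, 1 rose and 0 fell among histones, 4 rose and 1 fell among p53 targets and 3 rose and 0 fell in the BCL2 family. MYC target rises numbered 2 without D419N replicate 2 and 3 without WT replicate 2 or D419N replicate 1 or 4. MYC target falls numbered 4 without WT replicate 2 or 3 or D419N replicate 1, 2 or 3. G2/M falls numbered 1 without WT replicate 1 or 3 or D419N replicate 1, 3 or 4 and 2 without WT replicate 2. Replication rises numbered 3 without WT replicate 3. Replication falls numbered 2 without D419N replicate 2. Histone rises numbered 0 without WT replicate 1 or 2 or D419N replicate 1, 2 or 3 and 1 without D419N replicate 4. Histone falls numbered 0 without WT replicate 2 or 3 or D419N replicate 1 or 2 and 7 without WT replicate 1. p53 target rises numbered 1 without D419N replicate 1 or 3 and 2 without WT replicate 1 or D419N replicate 2. p53 target falls numbered 2 without WT replicate 3 and 3 without D419N replicate 3. BCL2 family rises numbered 1 without WT replicate 1 or D419N replicate 1. BCL2 family falls numbered 1 without WT replicate 2 or D419N replicate 1 or 2.

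Of 29 unfolded protein response genes, 5 rose and 4 fell (6 and 5 over the list alone), with Sel1l higher (0.48 ± 0.08) and Mthfd2 lower (-0.56 ± 0.12). Of 20 hypoxia genes, 5 rose and 3 fell (also over the list alone), among them Higd1a (-0.26 ± 0.06). Of 24 cholesterol synthesis genes, 1 rose and 3 fell (none and 2 over the list alone), with Mvk at -0.63 ± 0.12. Of 11 NOTCH target genes, Myc and Notch2 (0.67 ± 0.09) rose and none fell (2 over the list alone). In antigen presentation, 1 of 18 MHC class I genes rose and 6 fell (2 and 6 over the list alone), the falls including the immunoproteasome genes Psmb8 (-0.33 ± 0.06), Psmb9 (-0.45 ± 0.07), Psmb10 (-0.36 ± 0.06) and Psme1 (-0.35 ± 0.05). None of that list passed with the offset. Of 14 MHC class II genes, 1 rose, Rfx5 (0.32 ± 0.07), and 2 fell (also over the list alone). After the offset, 1 rose and 2 fell in the unfolded protein list, 3 rose and 3 fell in hypoxia, 1 rose and 1 fell in cholesterol synthesis, 2 rose and 0 fell among NOTCH targets and 1 rose and 0 fell in class II. Neither Sel1l (0.11, adjusted p = 0.258) nor Rfx5 (0.14, adjusted p = 0.167) was among these rises. Unfolded protein rises numbered 2 without D419N replicate 1, 2 or 3 and 3 without D419N replicate 4. Unfolded protein falls numbered 2 without WT replicate 2. Hypoxia rises numbered 3 without WT replicate 2 or 3 or D419N replicate 2. Hypoxia falls numbered 1 without WT replicate 2 or 3 or D419N replicate 2. Cholesterol rises numbered 0 without D419N replicate 1, 2, 3 or 4 and 4 without WT replicate 1. Cholesterol falls numbered 5 without D419N replicate 4. NOTCH falls numbered 1 without WT replicate 1 or D419N replicate 4. Class I rises numbered 0 without WT replicate 2 or 3 or D419N replicate 1, 2 or 3 and 3 without WT replicate 1. Class II rises numbered 2 without WT replicate 1. Class II falls numbered 0 without D419N replicate 1 or 3 and 1 without WT replicate 1 or D419N replicate 2.

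None of the measured T cell (5), NK cell (1), macrophage (6), neutrophil (1) or erythroid (2) markers passed, and no platelet marker was measured. With the offset, the macrophage markers Cd68 (1.20, adjusted p = 0.0479) and Apoe (0.59, adjusted p = 0.00907) rose and Ctsb fell (-0.43, adjusted p = 0.00923), from 0.95, 0.30 and -0.19 without it. Of 2 dendritic cell markers Cst3 fell (-0.37 ± 0.08), of 5 stromal markers Sparc rose (2.05 ± 0.44, from 0.419 to 1.72 CPM; 3 rose over the list alone), and of 4 host plasma cell markers Mzb1 and Ighg2b (-2.36 ± 0.54, and -1.45 without WT replicate 1) fell. The single sex-linked gene measured, Kdm5d, did not pass (-0.14 ± 0.17), but did with the offset (-0.55, adjusted p = 0.0399). Cst3 and Mzb1 did not pass with the offset (-0.08 and -0.46, adjusted p = 0.559 and 0.0727). T cell marker falls numbered 1 without WT replicate 3 or D419N replicate 3. Macrophage marker rises numbered 2 without WT replicate 3. Dendritic marker rises numbered 1 without D419N replicate 4. Erythroid marker falls numbered 1 without D419N replicate 4. Stromal marker rises numbered 3 without D419N replicate 4. All libraries shared dominant immunoglobulin segments: Ighv5-12 took between 93.5% (95% Wilson interval 93.1 to 93.9, D419N replicate 1) and 95.2% (94.9 to 95.5, D419N replicate 4) of heavy variable counts. Igkv19-93 took between 89.0% (88.6 to 89.3, WT replicate 1) and 96.0% (95.7 to 96.2, D419N replicate 4) of kappa variable counts. These intervals cover counting error only.

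Across the 33 lists with at least 5 measured genes, 5 passed camera: immediate early genes, chromatin regulators and the germinal centre list upwards, and ribosomal protein and oxidative phosphorylation genes downwards. None passed with an estimated correlation, where 2 lists had an unadjusted p below 0.05 (chromatin regulators 0.00601, germinal centre 0.0168) and fry passed 5, the interleukin 4 targets in place of the immediate early genes. With the length and GC offset 7 passed, the 5 above together with mature follicular genes and NF-kB targets (adjusted p = 0.0376 and 0.00987). With the replicate block 8 passed, the same 5 together with the precursor B cell and adhesion lists upwards (adjusted p = 0.0356 and 0.0225) and the interferon list downwards (adjusted p = 0.0173). The JAK-STAT and adhesion lists passed upwards without WT replicate 1 (adjusted p = 0.0289 and 0.0402), and the interferon list passed downwards without WT replicate 2 or 3 (adjusted p = 0.0360 and 0.0454). WT replicate 1 stood apart in the interferon list, with a mean log2 CPM of 4.44 against 2.34 and 2.47 in WT replicates 2 and 3 and 2.34 to 3.55 in D419N. Without it, and with no block, the median turned from -0.59 to 0.32 and camera pointed upwards (adjusted p = 0.443), so no fall with genotype is drawn from these passes. Median, mean and camera direction differed in sign for 4 lists: cytokines (median 0.03, mean 0.08, camera down), checkpoint genes (-0.07, 0.05, up), DNA replication (-0.01, 0.00, up) and T cell markers (-0.17, 0.13, up). Leaving out single libraries, the T cell marker median ran from -0.38 (D419N replicate 4) to 0.10 (WT replicate 3).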

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

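The tests on the library name prefix, on heat shock genes, on host B cells, and on length and GC bias for the immediate early and follicular genes were chosen after the results were seen. The others in this part were set before their results were seen.

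In the 4 D419N libraries, 10 of 199 values (log2 CPM of named genes, list means and library measures) had 1 library far from the other 3, which is about the 1 in 20 that chance gives. The gap of the far library as a share of the range was 0.868 for Lars2 (lowest, D419N replicate 1), 0.874 for Pllp, 0.852 for Psmb9, 0.911 for Cd79b and 0.919 for Oas1a (all D419N replicate 4, lowest for Pllp and highest for the other 3). It was 0.896 for Nfil3, 0.839 for Bcl6 and 0.910 for Nr4a1 (all lowest in D419N replicate 3). The interferon response list mean had a gap of 0.955, highest in D419N replicate 4, and the replication-dependent histone mean 0.906, highest in D419N replicate 3.

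Short transcripts were lower and long transcripts higher in D419N. A length and GC bias of the libraries may not be the whole cause for the ribosomal protein genes. They stayed lower than 5 matched genes each by a median of -0.23 (95% bootstrap interval -0.24 to -0.19), and 32 of 38 fell with the offset. The matches, chosen on length, GC content and expression, were longer by a median of 0.27 on the log2 scale. Their gap in expression was not recorded, and ribosomal protein genes had the highest mean log2 CPM of the lists. The bias may account for much of the fall of the oxidative phosphorylation genes, at -0.0825 (-0.0987 to -0.0415), inside the margin around 0 set in advance. The interval excludes 0, and with the offset the list still passed camera downwards (adjusted p = 0.00137, median -0.12), so a small fall remained. For chromatin regulators the matched difference was 0.19 (-0.01 to 0.39), which leaves the bias open. Bootstrap intervals in this part resample genes, which are not independent, and do not measure the spread between libraries. More unspliced or nuclear RNA in the D419N libraries could also contribute, since genes annotated as sense intronic had a median log2 fold change of 1.15 (0.60 to 1.69, 28 genes). Small nucleolar RNA genes had a median of 0.58 (0.41 to 0.70, 93 genes) and antisense genes of -0.28 (-0.34 to -0.21, 190 genes). Among nuclear RNAs, Malat1 rose (1.83 ± 0.29) and Rn7sk fell (-4.38 ± 0.37). Rmrp (-4.87), Rpph1 (-2.64), Kcnq1ot1 (-1.83) and Snord104 (-1.52), named like Rn7sk because they were among the largest falls, went the way of Rn7sk. The library name prefix cannot be told apart from genotype, as 0 prefixes held both, and an effect of the STAT6 genotype on these genes also stays open.

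Of 30 immediate early genes 10 rose and 1 fell in D419N, and Myc rose. Length and GC bias is argued against as the whole cause, because the list median was 1.57 (1.16 to 2.16) with the offset and 1.49 without it. Medians over the length bins ran only from -0.34 to 0.42, so the trend was small beside the list median and the offset could move it little. Handling stress of the kind that raises heat shock genes stays open, with a median of 0.25 (-0.78 to 0.55) over 11 genes that went both ways, of which 3 are also on the immediate early list. The part played by WT replicates 1 and 2 stays open too, as the list median was 0.57 (0.14 to 1.22) against WT replicate 3 alone, above the 0.5 set in advance but with an interval that reaches below it. WT replicate 3 carried another name prefix than WT replicates 1 and 2, so its difference from them (list mean of 6.58 against 5.22 and 3.27 log2 CPM) also follows a prefix. The library name prefix (0 held both genotypes) cannot be told apart from the genotype, which may itself raise these genes.

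Fcer2a and 5 other of the 18 measured genes of the mature follicular list rose in D419N, while the list as a whole did not pass camera (adjusted p = 0.208). Length and GC bias is argued against as the whole cause for 5 of the 6 members that rose, which still passed with the offset. It may account for Zfp318, at 0.55 before and 0.05 after the offset. The 6 were picked by the uncorrected test of the same data, so this says nothing of the list as a whole. Host B cells carried through the CD19 selection stay open: heavy variable counts outside the 2 leading segments were rarer in every D419N library (0.0401 to 0.0589%) than in any WT library (0.0740 to 0.142%), which goes against them. The group means were 0.0508% and 0.104% (a difference of -0.0529, two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0408), but they rested on 5 to 20 counts per library. Kappa variable counts outside the 2 leading segments ran the other way and overlapped, at 4.20 ± 2.02% in D419N (SD, n = 4) and 2.93 ± 1.74% in WT (SD, n = 3; a difference of 1.27, two-sided exact permutation p = 0.457). Single libraries weighed on both kappa means. D419N replicate 2 held 7.05%, and the other D419N libraries 2.32 to 3.93%. WT replicate 2 held 4.91%, and WT replicates 1 and 3 held 1.69 and 2.18%. Single segments carried much of these shares: Igkv5-43 took 3.85% in D419N replicate 2, Igkv1-88 2.09% in D419N replicate 4 and Igkv4-71 1.20% in WT replicate 2. A share carried by single segments need not come from a mix of host B cells, so the kappa share cannot decide. The confounded library name prefix was not tested for these genes in particular, and a genotype effect may hold but stays untested.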

How the results depend on the processing

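The length and GC offset, the runs without WT replicates 1 and 2 or without ribosomal RNA repeat and structural RNA genes, and the offset with the replicate block were chosen after the data were seen; all other settings were planned. The count of changed genes (4077) stayed within 1.5-fold, from 3628 to 4312, under the other normalizations, filters and tools and without receptor segments or structural RNA genes. The balance of directions moved with the scaling, at 1713 higher and 2577 lower under upper-quartile factors and 2114 and 1869 under RLE factors. Leaving out 1 library gave 2865 to 3944 changed genes, 1514 to 2165 higher and 1351 to 1898 lower, a Stat6 log2 fold change of 0.37 to 0.44 and 5 to 7 passing lists. The replicate block gave 2682 changed and 1193 lower genes and 8 passing lists. A test against a fold of 1.5 gave 113 genes (105 higher, 8 lower), since it asks for a larger change. The length and GC offset gave 2139 (969 higher, 1170 lower), and with the replicate block 797 (422 higher, 375 lower). Without WT replicates 1 and 2, 2234 genes changed and 823 were lower, with fewer samples. With a correlation estimated for each list, 0 lists passed, where fry passed 5. Stat6 stayed higher and past the threshold in every setting that tested it for any change. Its rise (log2 fold change 0.39) was below 1.5-fold, so it could not pass the test against that fold.

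Of 155 named genes besides Stat6, the offset left 101 with the same call, weakened 43, strengthened 5 and reversed 6. The offset with the replicate block kept the fewest, with 77 the same, 67 weakened, 4 strengthened and 7 reversed. With the offset, the reversed values were -0.172 for Il4ra, -0.120 for Cd93, -0.106 for Utp20, 0.0360 for Birc5, 4.96e-05 for Bax and 0.0477 for Cd2. With the offset and the replicate block they were -0.224 for Il4ra, -0.144 for Cd93, -0.132 for Utp20, 0.0614 for Birc5, 0.0217 for Bax, 0.0405 for Cd2 and 0.0411 for Derl3. Without WT replicates 1 and 2, Igtp was 0.0839, Cd8b1 0.0153 and Kdm5d 0.0371. Kdm5d was 0.108 without WT replicate 1 and, over single omissions, ran from -0.255 to that value, while Il4ra ran from -0.0344 without WT replicate 3 to 0.207. The cause of these reversals was not tested. Genes below about 1 CPM rest on few counts, and depth limits their folds.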

Other observations

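The splits below were planned before their results were seen; the other values in this part were looked at after the data were seen and carry no test unless one is named.

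Interferon response genes differed between libraries of the same genotype. Of 30 measured genes, 29 lay above their mean over the 7 libraries in WT replicate 1 and 28 in D419N replicate 4, against 2 to 5 in each of the other libraries. The median deviation was 1.47 on the log2 scale in WT replicate 1, 0.58 in D419N replicate 4 and between -0.47 and -0.31 elsewhere. The list median between genotypes was -0.59, and 0.32 without WT replicate 1. D419N replicate 4 also held 152 counts (3.98 for each 1e6 counts) over the 17 T cell markers too low to test, where the other libraries held 18 to 30 counts (0.628 to 1.22).

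Rare kappa variable segments differed between libraries. Igkv5-43 took 3.85% of kappa variable counts in D419N replicate 2 (95% Wilson interval 3.59 to 4.12) and at most 0.0580% (0.0315 to 0.107) in any other library. Igkv4-86 took 1.39% (1.23 to 1.58) in D419N replicate 1 and Igkv4-71 took 1.20% (1.06 to 1.37) in WT replicate 2. Igkv4-59 ranged from 0.539% (0.458 to 0.634) in D419N replicate 4 to 9.36% (9.03 to 9.69) in WT replicate 1. Ighv9-4, the second heavy variable segment, took 4.69% (4.40 to 5.01) to 6.45% (6.03 to 6.89).

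Classes of non-coding RNA moved apart. Of 93 small nucleolar RNA genes, 17 rose and 6 fell (median log2 fold change 0.58), and of 28 sense intronic genes 15 rose and 1 fell. Among 201 lincRNA genes 13 rose and 29 fell (median -0.21), and among 190 antisense genes 6 rose and 17 fell (median -0.28). Nuclear RNAs went both ways, with Malat1 higher (1.83 ± 0.29, edgeR adjusted p = 0.00239) and Rn7sk lower (-4.38 ± 0.37). Rmrp, Rpph1, Kcnq1ot1 and Snord104, among the largest falls, were lower too. The mitochondrial ribosomal RNAs mt-Rnr1 (-1.33 ± 0.13) and mt-Rnr2 (-0.87 ± 0.08) fell, while mitochondrial coding genes took 2.03 ± 0.138% of counts in D419N (SD, n = 4) and 1.72 ± 0.0753% in WT (SD, n = 3; exact permutation p = 0.0286, the smallest possible). The sources do not say whether RNA was selected by poly-A or depleted of ribosomal RNA, and raw reads would be needed to tell what the falls of ribosomal and other structural RNAs mean.

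Chance was weighed by regrouping the 7 libraries into 3 and 4 in all 35 ways. For the number of changed genes (4077), 1 split, the real one, gave as many, and the highest of the others was 3. The real split also stood alone for higher genes (2027 against at most 0) and lower genes (2050 against at most 3), with 1 split each. A share of 1 in 35 is the smallest possible, so these splits alone cannot exclude chance. Each other split mixes the genotypes, which puts the group difference into the spread within groups and lowers its count. Nor can the splits tell genotype from library name prefix. For passing lists, 32 of 35 splits gave at least the 5 of the real split, with up to 20 in another, so chance cannot be excluded for that count.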
